A study of Mus musculus with 12 samples.

How the data were processed

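RNA was measured in 12 mouse libraries that fall into 8 groups by their labels. The 5 bulk libraries hold endothelial cells isolated from NSCLC (3) and SCLC (2) tumours, and the labels do not say how the cells were isolated. The 7 single-cell libraries hold SCLC tumour tissue. Of these, 2 were labelled sgIgfbp5 and 1 sgScr, made with a 5′ kit, and 1 each was labelled sgIgfbp5 with anti-PD-1, sgScr with anti-PD-1, OSI-906 with anti-PD-1 and OSI-906, made with a 3′ kit. Per the labels, tissue was digested with collagenases, filtered, and cleared of red blood cells by lysis. The series describes the guide tumours as grown from SCLC organoids with an Igfbp5 knockout, placed orthotopically or under the skin.

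The authors deposited a bulk table of raw counts for 24421 gene symbols, aligned with STAR 2.6.0 to mm10 per the labels. The read counter and the annotation are not given in the sources used here. The authors also deposited a DESeq2 table (version not given in the sources used here) whose signal columns are the counts divided by 1 size factor per library, a ratio that was checked on the values. The same deposited table gives a log2 fold change made by the authors with DESeq2, which its sign against the signal columns shows to be SCLC over NSCLC. Its p-value column holds unadjusted values made by the authors with DESeq2. The single-cell files hold UMI counts per gene and cell made by the authors with Cell Ranger, 7.0.1 per the labels and 7.1.0 per the file headers of sgIgfbp5 replicate 1, with 28001 features and barcodes already called as cells. Of the features, 65 repeat a symbol, and a gene named by its symbol is the first of these. Identifiers and positions of named bulk genes come from GENCODE vM21 by symbol. List members that the files hold under an older symbol were matched through RefSeq synonyms, and members found under no symbol (the T cell receptor constant genes among them) were left out.

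Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr, TMM scaling, a robust quasi-likelihood fit of the group, and Benjamini-Hochberg adjustment at 0.05. CPM of genes taken from the edgeR fits are on TMM-scaled library sizes. All other CPM are on unscaled totals, among them marker sums, levels with Poisson intervals and the levels under other observations. The same gene can therefore have slightly different values in different passages. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and with fry. Fry's directional test passed no list, with a smallest adjusted p of 0.0906 in bulk (neuroendocrine tumour genes) and of 0.916, 0.546 and 0.527 in tumour-like, T-like and macrophage-like cells. A list needed 5 measured members. An exact permutation test of 3 against 2 libraries cannot give a p below 0.1, so shares and sums are given as values.

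Single cells were processed in Python 3.11.15 with scanpy 1.11.5 (Scrublet), scikit-learn 1.9.0 (neighbours), python-igraph 0.11.9 (Leiden), numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. Cells needed 300 genes, 500 UMIs and at most 15% mitochondrial UMIs. The cells with the highest Scrublet scores were removed as doublets, at 0.8% per 1000 cells of the library. Of 8842, 13937 and 11781 barcodes, 8151, 12362 and 10634 cells were kept in sgIgfbp5 replicates 1 and 2 and sgScr, with median UMIs of 5652, 3065 and 4460. Of 12187, 7515, 14365 and 13227 barcodes, 10729, 6675, 12471 and 11558 were kept in sgIgfbp5 with anti-PD-1, sgScr with anti-PD-1, OSI-906 with anti-PD-1 and OSI-906, with median UMIs of 5053, 3087, 10902 and 16265. Counts were scaled to 10000 per cell and logged. The 5′ libraries, the guide libraries under anti-PD-1 and the OSI-906 libraries were clustered as 3 sets on 2000 variable genes, 30 principal components and 20 neighbours, with Leiden clustering at a resolution of 1 and a seed of 1. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and Igfbp5 were kept out of the variable genes. A cluster was named from the marker lists when at least 3 markers of a cell type were 2-fold over the other cells and each in 5% of its cells, with a mean log2 fold over all markers of 1.5, and is called "like" that cell type. Clusters left over were named tumour-like by 3 neuroendocrine markers 2-fold over the cells named so far. Cells outside tumour-like clusters were clustered again and named by the same rules. Cluster numbers of tumour-like cells are those of the first clustering unless stated, and those of other classes are of the second. A cluster stayed unnamed where its leading genes held more markers of another type, or where it had few UMIs and no marker of its type among them. The clustering sets and the naming thresholds were decided after the data were seen.

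Cells are not replicates, so UMIs were summed per class and library. The 5′ set (2 libraries labelled sgIgfbp5 against 1 sgScr) was fitted as in bulk (with the robust option, which the written plan did not state) wherever every library had 20 cells of a class, with 1 residual degree of freedom and the lone sgScr library assumed to vary like the others. With 1 library per group no test was run. There, values are CPM of the class with exact Poisson 95% intervals, ratios are of CPM plus 10, and a list's median is placed among 10000 random lists matched on expression in 20 bins. Random lists hold genes drawn singly, so a list whose members move together can reach an extreme between any 2 libraries. Even a small median can do so, and the placement is a description and no test. Shares of cells carry exact Clopper-Pearson intervals, T-like share ratios carry log-normal intervals, and a count of 0 allows a level of up to 3 counts of the total. The labels describe cells for all 7 libraries. Ribosomal protein genes took 1.05% to 1.54% of UMIs in the 5′ and guide libraries against 14.2% and 17.1% in the OSI-906 libraries, a low share that nuclei also show. Whether some libraries hold nuclei is left open, and in that case their CPM and shares are those of nuclei. Libraries of different kits stand side by side only as values, in figures and in the ranges of undescribed features, and no ratio or test sets one against the other. The OSI-906 and guide libraries under anti-PD-1 were compared only as values, since they share a kit but the labels do not name the guide of the OSI-906 tumours.

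Before the data were examined, the groups, the comparisons, 27 gene lists, 25 marker lists, 45 alternatives and a rule for the genes to name were written down. The rule took, in bulk, the 10 higher and 10 lower genes with the largest change among those past the threshold with a mean log2 CPM of 2 or more whose group ranges do not overlap, leaving out predicted genes, antigen receptor segments, and mitochondrial and ribosomal protein genes. It took 5 and 5 in single-cell comparisons, with 100 UMIs where libraries stood 1 against 1. It added from each list the members with the smallest adjusted p (or, 1 against 1, the largest ratio with 30 UMIs), and a fixed set of genes of the IGF pathway, vessel barrier, adhesion and T cells. Because no bulk gene passed with edgeR, the bulk part named none, and Tnxb, Ptprf, Krt7, Lama1, Col7a1 and Hmga2 were chosen after their values were seen, as were Stambpl1, Fgf14, Atp6v0d2 and Ccr2 in single cells. LUCI2LTR, CAS9, V2TC and the genes given for clusters in the closing observations were also chosen after their values were seen. A further 3 alternatives were added after the data were seen. The values of 1 gene are not reported here.

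Alternatives were size-factor and upper-quartile scaling, DESeq2 1.42.0, other low-count filters (none, or 10 counts in 2 libraries), a non-robust fit, the replicate number as a block, leaving out each library, an estimated list correlation, a looser cell filter (200 genes, 25% mitochondrial), no doublet removal, Leiden resolutions of 0.5 and 2, and pseudocounts of 1 and 50. The pipelines were tested on simulated data with 200 genes changed by a known fold. Leaving out an SCLC library leaves 1 against 3, and the lone library is assumed to vary like the others. Xist and Y-linked genes were used only to check samples. Barcodes that failed the filters were left out, and guide sequences were not analysed here.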

Results

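The data describe the vessels, tumour cells and immune cells of mouse lung tumours at the level of RNA. Bulk RNA-seq covered endothelial cells isolated from small-cell lung cancer (SCLC, 2 libraries) and from non-small-cell lung cancer (NSCLC, 3 libraries). Droplet single-cell RNA-seq covered 7 tumour libraries in 6 groups. A 5′ kit gave 2 libraries from tumours labelled sgIgfbp5 and 1 from tumours labelled sgScr, the guide control. A 3′ kit gave 1 library each of sgIgfbp5 with anti-PD-1, sgScr with anti-PD-1, OSI-906 with anti-PD-1, and OSI-906 alone. Anti-PD-1 is an antibody that blocks the T cell checkpoint receptor PD-1, and OSI-906 (linsitinib) inhibits the IGF1 receptor and the insulin receptor. The labels do not name the guide of the OSI-906 tumours. The bulk libraries held 17258655, 19157208 and 12632289 counts for NSCLC replicates 1, 2 and 3, and 21713863 and 16465550 for SCLC replicates 1 and 2. The single-cell libraries held 62618925, 56974298 and 64689999 unique molecular identifiers (UMIs) for sgIgfbp5 replicates 1 and 2 and sgScr. The 3′ libraries held 75743323 for sgIgfbp5 with anti-PD-1, 29346231 for sgScr with anti-PD-1, 185019412 for OSI-906 with anti-PD-1 and 233262818 for OSI-906. Nothing in the labels says that replicates come from separate animals, so every p-value here measures only the spread between these samples. Intervals and floors cover counting error only.

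The bulk comparison asked how tumour endothelium of SCLC differs from that of NSCLC, a question the series ties to a barrier-like vessel wall. The list of neuroendocrine tumour genes ranked higher in the SCLC preparations (adjusted p 6.24e-07, and adjusted p = 0.628 with an estimated correlation), while the lists of barrier transporters, endothelial junctions and leukocyte adhesion did not pass in either direction. Cgn, which encodes the tight-junction adaptor cingulin, had 44.0 and 58.3 CPM (counts scaled to library size) in SCLC against 1.52 to 2.52 in NSCLC. Igfbp2, a secreted IGF-binding protein gene, had 97.5 and 17.4 CPM against 0.229 to 0.631. Igfbp5, the binding-protein gene that the guides target in the other tumours, had 284 and 940 CPM in SCLC and 196, 396 and 417 in NSCLC, so its ranges overlapped. Lama1 and Col7a1, genes of a basement membrane laminin and of anchoring fibrils chosen after their values were seen, had 13.6 and 11.7 and 13.1 and 13.1 CPM in SCLC against 73.2 to 119.6 and 87.0 to 174 in NSCLC.

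With edgeR, 0 of 14697 genes passed an adjusted p of 0.05, and 1680 had an unadjusted p under 0.05, of which 1310 were higher and 370 lower in SCLC. DESeq2 called 825 of 15899 genes (691 higher, 134 lower), and p-values in the authors' deposited table, adjusted here, gave 774 of 18763 (650 higher, 124 lower). Leaving out SCLC replicate 1 gave 60 genes with edgeR, all 60 higher, and leaving out SCLC replicate 2 gave 98 (92 higher, 6 lower). These 2 fits hold 1 SCLC library, which is assumed to vary like the NSCLC libraries, so they carry no measure of the spread within SCLC. In simulated data of this size edgeR called 1.49% of 67 genes changed 2-fold, 31.3% of 67 changed 4-fold and 74.2% of 66 changed 8-fold. There DESeq2 called 91 of 14494 unchanged genes, beside 10, 50 and 63 genes changed 2-fold, 4-fold and 8-fold. Many of its calls were thus false in this simulation, so its counts and small p-values in bulk are weak support.

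The log2 fold changes (SCLC over NSCLC, from edgeR) put these genes in order. Cgn (ENSMUSG00000068876; chromosome 3, 94760069 to 94786492 on mm10) had 4.69 (SE 0.34, adjusted p 0.0712, and 1.04e-23 with DESeq2). Igfbp2 (ENSMUSG00000039323; chromosome 1, 72824503 to 72852474) had 6.96 (SE 0.90, adjusted p 0.118, and 1.14e-13 with DESeq2). Igfbp5 (ENSMUSG00000026185; chromosome 1, 72857932 to 72874884) had 0.86 (SE 0.60, adjusted p 0.667). The following genes were chosen after their values were seen. Tnxb, a matrix glycoprotein gene, had 2.93 (SE 0.21, adjusted p 0.0712), Ptprf, a receptor phosphatase gene, had 2.68 (SE 0.21, adjusted p 0.0771), and Krt7, an epithelial keratin gene, had 4.42 (SE 0.41, adjusted p 0.111). Lama1 had -2.98 (SE 0.32), Col7a1 -3.38 (SE 0.39) and Hmga2, a chromatin protein gene of embryonic and tumour cells, -8.00 (SE 1.17), with adjusted p-values of 0.111, 0.111 and 0.149. Leaving out SCLC replicates 1 or 2 took the adjusted p to 0.0334 or 0.0382 for Cgn, to 0.0334 or 0.0382 for Tnxb, to 0.0334 or 0.0382 for Ptprf and to 0.0464 or 0.0439 for Krt7, and for Igfbp2 it was 0.0352 without SCLC replicate 2. In these fits the spread comes from the NSCLC libraries alone, so the p-values add no support to those of all libraries.

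**Figure D1:**
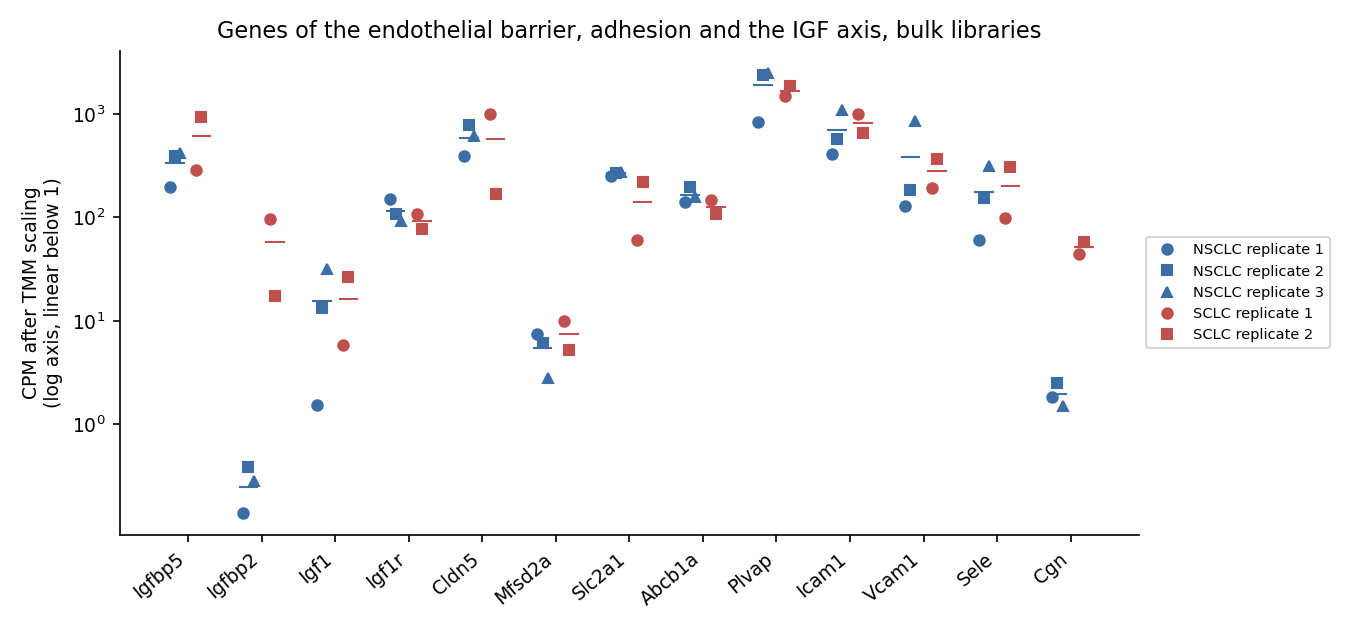
CPM (log axis above 1) of named genes in each bulk endothelial library, NSCLC (3 libraries) and SCLC (2 libraries), one point per library. Cgn sits at 44.0 and 58.3 in SCLC against at most 2.52 in NSCLC, whereas the Igfbp5 points of the groups overlap.

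Markers of other cell types moved with the groups, and differently in each SCLC library. Markers of alveolar type 2 cells, which make surfactant, summed to 10694 CPM in SCLC replicate 1 and 127 in replicate 2 against a mean of 205.9 in NSCLC. Alveolar type 1 markers summed to 14.6 times the NSCLC mean in replicate 1 and 0.550 times in replicate 2, club or ciliated markers to 30.2 and 2.57 times, and macrophage markers to 8.88 and 1.15 times. T cell markers summed to 6.40 and 1.34 times, NK to 10.9 and 0.448, B to 5.57 and 5.96, and neutrophil to 3.50 and 0.561 times the NSCLC mean. Fibroblast markers stood the other way, at 0.726 times in replicate 1 and 5.23 in replicate 2, as did mesothelial (0.853 and 26.5) and keratinocyte markers (3.71 and 129). Mural markers summed to 1.95 and 3.91 times, other epithelial to 2.01 and 4.23, neuroendocrine to 1.47 and 2.97, platelet to 8.87 and 2.38, and glial to 3.51 and 8.46 times. Alveolar macrophage markers lay at 1.05 and 1.34 times, dendritic at 0.531 and 1.16, mast or basophil at 2.27 and 0.345, plasma at 1.04 and 2.82, and plasmacytoid dendritic at 3.14 and 3.24 times. Endothelial markers summed to 14208 and 8954 CPM in SCLC and to 7068, 14326 and 13886 in NSCLC, and lymphatic endothelial markers to 1170.1 and 1396 against 1319.6 to 1797. Erythroid and muscle markers stayed under 10 CPM in every library.

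**Figure D2:**
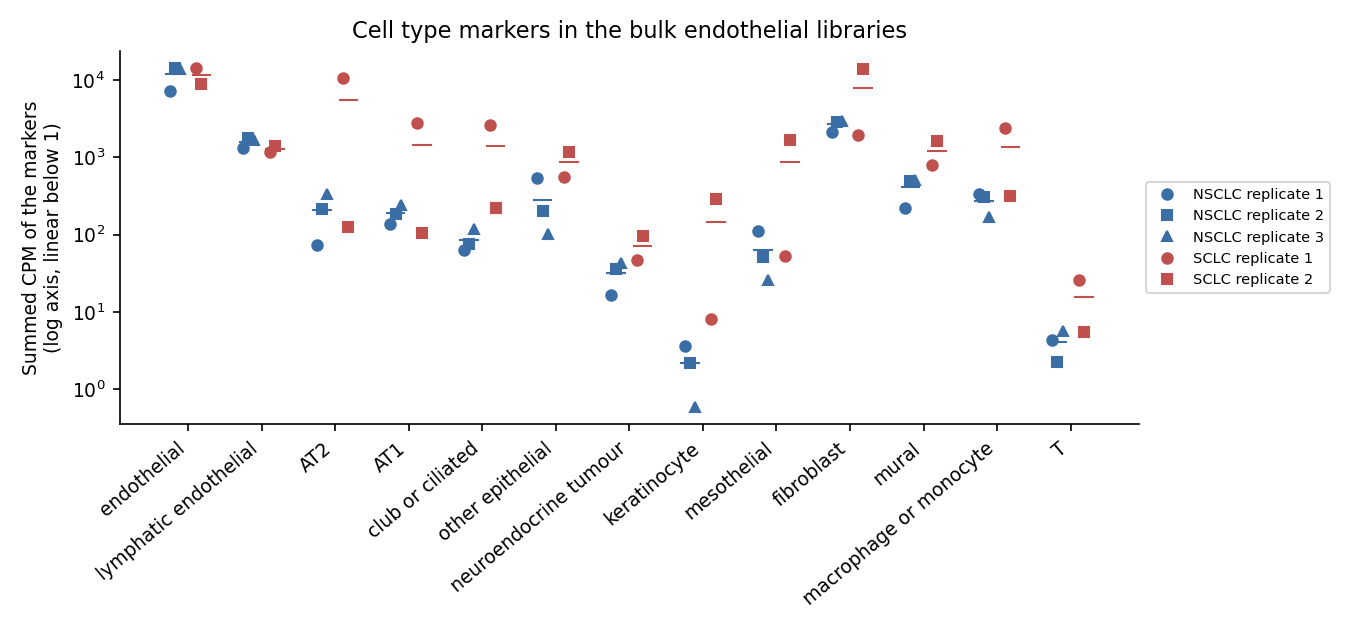
Summed CPM (log axis above 1) of the marker genes of each cell type in each bulk library, one point per library. Alveolar type 2 markers reach 10694 in SCLC replicate 1, and fibroblast markers reach 13872 in SCLC replicate 2.

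Of the 27 gene lists, 6 passed the camera test at its preset correlation, and none did with an estimated correlation. The estimated-correlation test rests on 3 residual degrees of freedom, so its failures are weak evidence. Neuroendocrine tumour genes rose (12 of 15 higher, median log2 fold change 3.41, adjusted p 6.24e-07, and adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 9 passed, and none did over all genes with edgeR. Its members Nkx2-1, a lung lineage factor that alveolar cells also express, and Foxa2, a factor of airway epithelium, had 71.0 and 19.3 and 12.5 and 4.72 CPM in SCLC against at most 3.52 and 0.573 in NSCLC, beside the alveolar and club markers above. Nkx2-1 had an adjusted p of 0.0382 without SCLC replicate 2, in a fit whose spread comes from NSCLC alone and whose 1 SCLC library, replicate 1, has alveolar type 2 markers at 51.9 times the NSCLC mean. T cell cytotoxicity genes rose (20 of 20 higher, median 1.69, adjusted p 0.0150, and adjusted p = 0.995 with an estimated correlation), with the chemokine genes Ccl4 at 24.7 and 3.94 CPM against 1.68 to 3.33 and Ccl3 at 32.4 and 3.75 against 1.60 to 4.07. T and NK markers were highest in SCLC replicate 1, and without it this list ranked lower instead (adjusted p 0.631); without NSCLC replicates 1 or 2 its adjusted p was 0.0540 or 0.176.

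Lists of growth, low oxygen and vessel sprouting ranked lower in the SCLC preparations. The NSCLC libraries also held RNA of epithelial and tumour genes, falling from replicate 1 to 3. On unscaled totals Krt18, an epithelial keratin gene, had 268, 86.0 and 33.0 CPM there against 64.9 and 213 in SCLC. Hmga2 had 287, 113 and 34.1 against 0.60 and 0.55. Whether the lists below fell in endothelial cells or through RNA of other cells in NSCLC was not tested. Proliferation genes fell as a list (23 of 27 lower, median -0.44, adjusted p 1.26e-04), with 0 members at an unadjusted p under 0.05. Cenpe and Aurkb, a mitotic motor and a mitotic kinase gene, had 6.82 and 28.8 and 5.33 and 19.6 CPM against 39.2 to 46.8 and 19.9 to 34.6 (adjusted p 0.509 and 0.538). Hypoxia and glycolysis genes fell (17 of 21 lower, median -0.69, adjusted p 2.90e-04), with Ankrd37, a hypoxia-induced gene, at 18.9 and 22.2 CPM against 38.9 to 52.0, and Slc2a1, the glucose transporter gene, at 60.7 and 218 against 252 to 276. Tip cell and angiogenesis genes fell (22 of 27 lower, median -0.51, adjusted p 0.00116), with Trp53i11 at 189 and 353 CPM against 576 to 1324 and Adm, the adrenomedullin gene, at 26.1 and 29.2 against 34.8 to 95.1. Non-neuroendocrine tumour genes fell (15 of 15 lower, median -0.56, adjusted p 0.00116), with Ctgf, a YAP target gene, at 289.6 and 344 CPM against 433 to 746. For these 4 lists adjusted p = 0.995 with an estimated correlation, and 0 members passed over all genes or over the list alone with edgeR. Each lost its call without SCLC replicate 1 (adjusted p 0.350 with the direction turned for proliferation, 0.361, 0.167 and 0.331 in this order), the tip cell list also without NSCLC replicate 3 (0.0512), and without SCLC replicate 2 the number of lists past the test was 10.

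The lists for the vessel barrier did not pass. Barrier transporters had 12 of 21 members higher (median 0.36, test direction down, adjusted p 0.934), with Mfsd2a, a lipid transporter gene of the blood-brain barrier, at 9.88 and 5.21 CPM against 2.78 to 7.51, and Abcb1a, an efflux pump gene, at 146 and 108 against 139 to 196. Its member Spock2, a matrix proteoglycan gene, had 113 and 40.6 CPM against 1.18 to 34.3. Endothelial junction genes had 11 of 21 lower (median -0.03, mean 0.38, test direction down, adjusted p 0.962). Cldn5, the main claudin of tight endothelium, had 988 and 167 CPM against 388 to 775, and 2 members, Cgn and Lsr, passed when adjusted over the list alone. Both also mark epithelium, whose markers stood at 2.01 and 4.23 times the NSCLC mean. These markers summed to 559.8 and 1180.5 CPM in SCLC and to 531.5, 203.9 and 102.2 in NSCLC replicates 1, 2 and 3. SCLC replicate 1 thus stood near NSCLC replicate 1. Wnt/beta-catenin targets (14 of 18 higher, median 0.52) had an adjusted p of 0.788, with Apcdd1, a Wnt inhibitor gene, at 13.03 and 8.18 CPM against 23.9 to 30.1. This list passed downward without SCLC replicate 1 (adjusted p 0.0180) and upward without SCLC replicate 2 (0.00214), with adjusted p = 0.969 and 0.518 with an estimated correlation in these fits, which hold 1 SCLC library each. Caveolae and fenestrae genes (7 of 11 higher, median 0.18, test direction down) had 0.962, with Plvap, the diaphragm gene of leaky vessels, at a log2 fold change of -0.18 (SE 0.56). Leukocyte adhesion genes (11 of 18 higher, median 0.21, test direction down) had 0.962, with Icam1 at 0.25 (SE 0.51), Vcam1 at -0.47 (SE 0.88) and Sele at 0.21 (SE 0.77), each an adhesion receptor gene for leukocytes, and Jam2, a junctional adhesion gene, at 172 and 142 CPM against 282 to 415.

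The remaining lists did not pass either. The adjusted p-values were 0.336 for basement membrane and matrix (12 of 20 lower, median -0.23), 0.336 for arterial (11 of 14 higher, 0.47) and 0.607 for venous endothelium (7 of 12 lower, median -0.13, mean 0.16). Lung capillary genes (13 of 19 higher, median 1.27) had 0.607, with Hpgd, a prostaglandin-degrading enzyme gene, at 1038 and 48.0 CPM against 15.9 to 41.7. The IGF axis (10 of 18 higher, median 0.17) had 0.738, and 3 members passed when adjusted over the list alone. Igf1r and Insr, the receptor genes of IGF1 and insulin, had log2 fold changes of -0.32 (SE 0.31) and -0.59 (SE 0.52). Chemokines (12 of 17 higher, 1.27) had 0.341, MHC class I (13 of 16 lower, -0.27) 0.738, MHC class II (6 of 8 lower, -0.28) 0.934, and interferon response (25 of 36 lower, median -0.29, test direction up) 0.971. TNF and NF-kB response (13 of 20 higher, 0.24) and checkpoint ligands (10 of 17 lower, -0.45) both had 0.738. T cell exhaustion (12 of 18 lower, -0.42) had 0.341, naive and memory T cells (11 of 16 higher, 0.55) 0.336, and regulatory T cells (7 of 12 lower, -0.11) 0.373, with 3 members past when adjusted over the list alone. Of these 3, Il1rl1, the IL-33 receptor gene, had 0.831 and 2.48 CPM against 18.5 to 34.0. Immune-activating macrophage genes (9 of 17 lower, -0.19) had 0.788, and immune-suppressive ones (13 of 22 higher, median 0.19, mean -0.01, test direction down) 0.971, with Spp1, the osteopontin gene, at 73.2 and 13.4 CPM against 213 to 7201. Some of these lists passed when 1 library was left out, which for SCLC leaves 1 library assumed to vary like those of NSCLC. Without SCLC replicate 1, lung capillary genes passed downward (adjusted p 0.0180), and chemokines (0.0346) and TNF and NF-kB response (0.0375) upward (adjusted p = 0.969 for each with an estimated correlation). Without SCLC replicate 2, lung capillary genes (7.45e-05) and naive and memory T genes (0.0473) passed upward, basement membrane and matrix downward (8.39e-05), and Hpgd had an adjusted p of 0.0397. With an estimated correlation these lists had adjusted p = 0.905, 0.810 and 0.905. Without NSCLC replicate 1, basement membrane and matrix (0.0194), MHC class I (0.0244) and interferon response (0.00710) passed downward (adjusted p = 0.838 for each with an estimated correlation). Without NSCLC replicate 3, chemokines (0.0455) and interferon response (3.60e-06) passed upward (adjusted p = 0.928 for each with an estimated correlation). Both also passed upward with the replicate number as a block (0.00195 and 4.67e-06, and adjusted p = 0.898 for each with an estimated correlation).

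The guide comparison without treatment asked what loss of Igfbp5 in tumour cells does to the tumour and its vessels and immune cells. Igfbp5 RNA itself ran against the labels. In tumour-like cells, named for neuroendocrine markers, Igfbp5 had 156 CPM (95% interval 153 to 159.6) and 168 CPM (164 to 172) in the libraries labelled sgIgfbp5, and 77.8 CPM (75.4 to 80.3) in sgScr. The edgeR log2 fold change was 1.03 (SE 0.15, adjusted p 0.120, and 5.13e-04 with DESeq2), higher in 2 of 2 libraries. Guide-made insertions and deletions need not remove the transcript, so this level says little about the protein. Every direction below is between the libraries labelled sgIgfbp5 and sgScr, and none is evidence on loss of the protein.

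**Figure D3:**
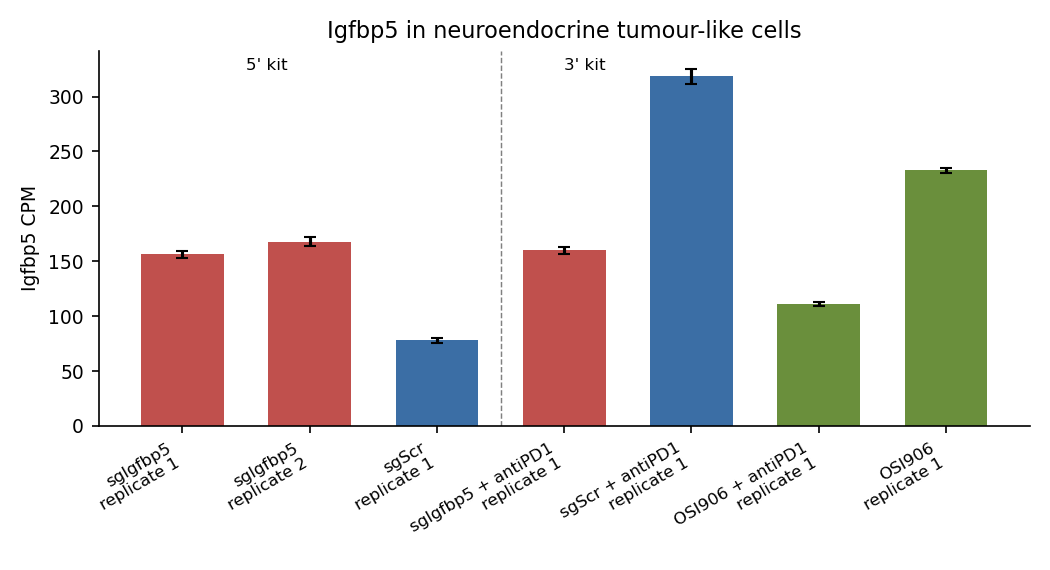
Igfbp5 CPM in tumour-like cells of each single-cell library, with exact 95% Poisson intervals for counting error. The 5′ libraries labelled sgIgfbp5 lie at 156 and 168 and sgScr at 77.8, while among the 3′ libraries sgIgfbp5 with anti-PD-1 lies at 159.9 and sgScr with anti-PD-1 at 318.

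Cell composition differed between the libraries labelled sgIgfbp5 as well as between the groups. T-like cells made up 0.478% (exact Clopper-Pearson interval 0.340 to 0.654) and 3.68% (3.36 to 4.03) of kept cells in sgIgfbp5 replicates 1 and 2, and 3.54% (3.19 to 3.90) in sgScr. Macrophage- or monocyte-like cells made up 1.02%, 3.67% and 3.01%, B-like cells 0.221%, 0.793% and 11.6%, and mesothelial-like cells 0.0123%, 0.0243% and 1.12%. Endothelial-like cells numbered 11, 287 and 42, or 0.135%, 2.32% and 0.395%. Tumour-like cells made up 93.8%, 64.4% and 74.8%, and cells in unnamed clusters 3.82%, 12.7% and 3.09%. Alveolar type 1-like cells numbered 12, 419 and 0, and 0 of 10634 cells allows a share of up to 0.0282%. An exact permutation test of 2 against 1 libraries cannot give a p below 0.33, so shares are given as values. Endothelial-like cells were under the 20 cells set for a test in sgIgfbp5 replicate 1, so their genes were not tested.

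**Figure D4:**
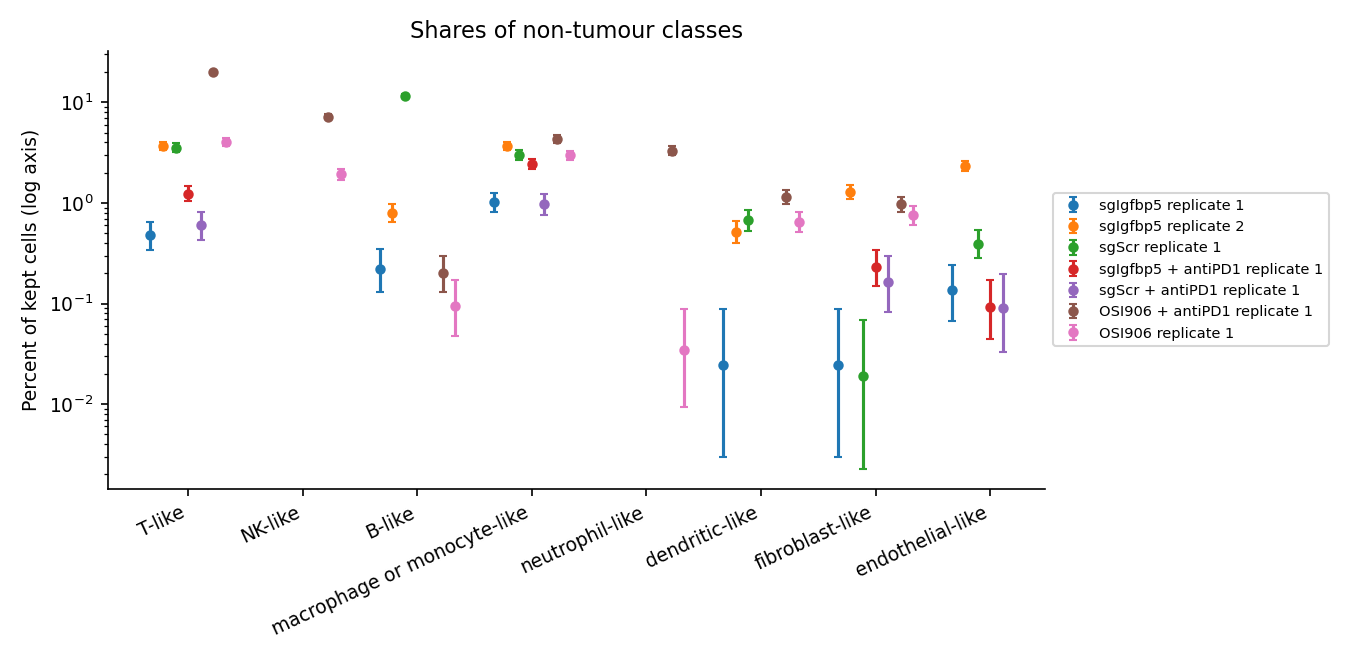
Percent of kept cells (log axis) in each named non-tumour class for each single-cell library, with exact 95% Clopper-Pearson intervals. T-like cells reach 3.68% in sgIgfbp5 replicate 2 among the 5′ libraries and 19.95% in OSI-906 with anti-PD-1 among the 3′ libraries, which are not compared across kits.

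In tumour-like cells, interferon-response and chemokine genes ranked lower, and hypoxia and glycolysis genes higher, in the libraries labelled sgIgfbp5. Interferon genes fell (29 of 31 lower, median -1.15, adjusted p 1.12e-04, and adjusted p = 0.833 with an estimated correlation), with Irf9, a transducer of interferon signals, at 5.83 and 7.57 CPM against 14.9. Chemokine genes fell (10 of 12 lower, median -1.20, adjusted p 0.0206, and adjusted p = 0.833 with an estimated correlation). Their levels were low, with Ccl2, a monocyte attractant, at 0.0562 and 0.181 CPM against 1.16. Of the lists of immune-cell genes that did not pass in these tumour-like cells, MHC class II had 8 of 8 genes lower (median -1.66, adjusted p 0.0690) and immune-activating macrophage genes 14 of 16 (median -0.87, adjusted p 0.0881). Immune-suppressive macrophage genes (10 of 19 lower, median -0.28, mean -0.08) and regulatory T cell genes (6 of 11 lower, median -0.08) went both ways. These stand beside 11.6% B-like cells in sgScr and 0.221% and 0.793% in the libraries labelled sgIgfbp5. Hypoxia and glycolysis genes rose (19 of 22 higher, median 0.34, adjusted p 0.00403, and adjusted p = 0.833 with an estimated correlation), with the glycolytic enzyme genes Gapdh at 112 and 103 CPM against 46.5 and Eno1 at 122 and 142 against 60.6. In these tumour-like cells Malat1, a nuclear RNA, took 0.720% and 0.575% of UMIs in the libraries labelled sgIgfbp5 against 1.01%, and ribosomal protein genes 1.5001% and 1.63% against 1.08%. By gene, edgeR called 0 of 18194, with 2322 at an unadjusted p under 0.05 (1124 higher, 1198 lower), while DESeq2 called 586 (280 higher, 306 lower). In simulated data of this size edgeR called 55.2% of 67 genes changed 2-fold and 98.5% of 66 changed 8-fold, but also 62 of 17490 unchanged genes. Stambpl1, a deubiquitinase gene chosen after its values were seen, had 16.4 and 20.4 CPM against 0.857 and was not called. The simulated spread may therefore differ from that of the data, and 0 calls do not show that changes are few. Igf1r had 165 and 367 CPM against 279.7. Different clusters held the tumour-like cells, with clusters 2 and 4 of the first clustering holding 53.4% and 31.3% in sgScr and at most 0.301% in the libraries labelled sgIgfbp5. Clusters 0, 2, 3 and 8, named tumour-like only in the second clustering, held 18.3%, 12.7%, 10.5% and 5.95% in sgIgfbp5 replicate 2. Each held at most 1.45% in replicate 1 and 0.289% in sgScr, so the sets of tumour-like cells compared differ.

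In T-like cells, 32 of 8616 genes passed, 11 higher and 21 lower, in the libraries labelled sgIgfbp5. Il7r, the IL-7 receptor gene of naive and memory T cells, rose to 1633 and 1394 CPM from 542 (log2 fold change 1.47, SE 0.28, adjusted p 1.32e-04). Tnfaip3, an inhibitor of NF-kB signalling, rose to 247 and 115 CPM from 33.2 (2.20, SE 0.53, adjusted p 0.0109), and Zfp36l2, an RNA-decay factor gene, rose as well (1.66, SE 0.39, adjusted p 0.00741). Nlgn1, a synaptic adhesion gene, rose to 13.7 and 134 CPM from 1.58 (5.78, SE 0.89, adjusted p 2.52e-07). T-like cells of sgIgfbp5 replicate 1 and sgScr held 74989 and 653964 UMIs, so 13.7 and 1.58 CPM are very few Nlgn1 UMIs. The size of this rise therefore rests mainly on sgIgfbp5 replicate 2. Without doublet removal the log2 fold change of Nlgn1 was 1.82. Fgf14, chosen after its values were seen, and Nrg3, also genes of neuronal cells, fell (-2.24, SE 0.30, adjusted p 9.36e-10, and -2.90, SE 0.47, adjusted p 1.61e-06). Of the 21 lower genes, 15 were higher-level in tumour-like cells of these libraries and all 21 had the same direction there. Of the 11 higher genes, 1 was higher-level in tumour-like cells and 6 had the same direction there. Carried-over RNA was not estimated for these libraries. Neuroendocrine tumour genes fell as a list in T-like cells (6 of 7 lower, adjusted p 0.0306, and adjusted p = 0.920 with an estimated correlation). Cd8a had 82.3 and 79.8 CPM against 75.8, Cd4 96.1 and 198 against 159.6, and Pdcd1, the PD-1 gene, 0 and 151 against 67.9. The 0 of Pdcd1 in sgIgfbp5 replicate 1 allows a level of up to 3 counts of its 74989 UMIs. No call rests on many cells, since sgIgfbp5 replicate 1 held 39 T-like cells. DESeq2 called 0 of 16315, with 43 at an unadjusted p under 0.05, and without doublet removal edgeR called 74 (34 higher, 40 lower). The calls of Il7r, Tnfaip3 and Nlgn1 ended without doublet removal (adjusted p 0.145, 0.102 and 0.0711), and those of Tnfaip3 and Zfp36l2 with no filter (0.143 and 0.0723).

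In macrophage-like cells, genes of alveolar macrophages and of recruited monocytes were among those past the test. Chil3 and Atp6v0d2, genes of alveolar macrophages and of lysosomal proton pumps, rose to 215 and 585 and to 831 and 1123 CPM from 9.59 and 52.3 (log2 fold changes 5.40, SE 0.53, adjusted p 7.34e-21, and 4.22, SE 0.48, adjusted p 5.68e-15). Gpnmb, a gene of lipid-laden macrophages, rose to 374 and 1154 from 161 (2.26, SE 0.42, adjusted p 1.07e-05). Ccr2, the receptor gene of recruited monocytes, fell to 13.2 and 10.2 CPM from 305 (-4.78, SE 0.45, adjusted p 6.27e-23), and Ccl2 fell to 23.2 and 1.70 from 140.4 (-4.29, SE 0.52, adjusted p 1.70e-13). Atp6v0d2 and Ccr2 were chosen after their values were seen. With DESeq2 Chil3, Atp6v0d2 and Ccr2 kept their calls (adjusted p 4.15e-09, 2.63e-14 and 6.01e-07), while Gpnmb and Ccl2 lost theirs (unadjusted p 0.0828 and 0.107). The looser cell filter ended the calls of Chil3, Gpnmb and Ccl2 (adjusted p 0.0530, 0.476 and 0.132), and a Leiden resolution of 2 those of Gpnmb and Ccl2 (0.603 and 0.0604). Folr2 and Lyve1, genes of tissue-resident macrophages, had 0 CPM in both libraries labelled sgIgfbp5 and 40.1 and 34.0 in sgScr, and had no adjusted p with DESeq2. Alveolar type 1-like cells numbered 12, 419 and 0 and alveolar type 2-like cells 1, 301 and 0 in sgIgfbp5 replicates 1 and 2 and sgScr, and mitochondrial genes took 0.197%, 0.172% and 0.524% of UMIs in their macrophage-like cells. The macrophage values therefore cannot separate the guide label from the lung tissue sampled, and Chil3 is itself on the alveolar macrophage marker list.

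By list, 9 ranked past the test in macrophage-like cells, each at its preset correlation only (adjusted p = 0.772 with an estimated correlation for all 9). With 1 residual degree of freedom the estimated-correlation test can hardly pass a list. Immune-activating genes had an estimated correlation of -0.0294, under the preset 0.01, yet their unadjusted camera p went from 2.40e-07 to 0.113. These failures therefore count neither for nor against the lists. Interferon genes fell (31 of 31 lower, 14 past over all genes and 25 adjusted over the list alone, median -1.49, adjusted p 5.35e-12), with Iigp1, an interferon-induced GTPase gene, at -1.87 (SE 0.39) and Mx1, an antiviral GTPase gene, at -1.97 (SE 0.42). By gene, DESeq2 ended the calls of Iigp1 (adjusted p 0.607) and Mx1 (unadjusted p 0.0593), and Mx1 also lost its call with the looser cell filter (adjusted p 0.781), at a Leiden resolution of 2 (0.864) and in the shared cluster described below (0.146). MHC class II genes fell (7 of 8 lower, 5 past over all genes and 6 adjusted over the list alone, adjusted p 1.28e-05), with Cd74, the invariant chain gene, at 258 and 263 CPM against 721 (adjusted p 0.00225, and 0.159 with DESeq2). This stands beside B-like shares of 0.221% and 0.793% in the libraries labelled sgIgfbp5 and 11.6% in sgScr. Carried-over RNA of B-like cells was not estimated. MHC class I genes fell (18 of 19 lower, adjusted p 1.92e-06), as did immune-activating macrophage genes (15 of 17 lower, 9 past, adjusted p 1.92e-06), chemokines (8 of 10 lower, adjusted p 9.78e-05) and proliferation genes (24 of 27 lower, adjusted p 5.33e-04). Cxcl9, a T cell attractant, had 9.93 and 16.1 CPM against 75.9 (adjusted p 1.17e-04, 0.878 with DESeq2 and 0.105 without doublet removal). T cell cytotoxicity genes (7 of 7 lower, adjusted p 3.59e-05) and naive and memory T genes (7 of 11 lower, adjusted p 0.0377) ranked lower, in libraries with T-like shares of 0.478%, 3.68% and 3.54% (sgIgfbp5 replicates 1 and 2 and sgScr) whose carried-over RNA was not estimated. IGF axis genes rose (8 of 8 higher, median 0.67, adjusted p 0.0222), with Igf1 at 420.4 and 365 CPM against 214.

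The gene test in macrophage-like cells called 369 of 10463 with edgeR, 143 higher and 226 lower, and 43 with DESeq2 (15 higher, 28 lower). Without doublet removal it called 374 (101 higher, 273 lower). Cluster 6 held 94.0% and 97.6% of macrophage-like cells in the libraries labelled sgIgfbp5 and 50.3% in sgScr, where cluster 16 held 49.7%, so the sets of cells compared differ. In cluster 6 alone, a setting chosen after seeing the data, 214 genes passed (110 higher, 104 lower), interferon genes fell (21 of 22 lower, adjusted p 1.74e-09, and adjusted p = 0.740 with an estimated correlation), and Arg1, an arginine-degrading enzyme gene that fell in the whole class (-1.69, SE 0.40, adjusted p 0.00167, and 0.996 with DESeq2), had 0.22, and Gpnmb had an adjusted p of 0.0732. Immune-suppressive genes did not pass in the whole class (12 of 21 lower, adjusted p 0.379), but rose in cluster 6 alone (11 of 16 higher, median 0.60, adjusted p 0.0369, and adjusted p = 0.740 with an estimated correlation). TNF and NF-kB response (8 of 12 lower, adjusted p 0.0206), hypoxia and glycolysis (13 of 19 lower, 0.0347) and neuroendocrine tumour genes (7 of 7 lower, 0.0121) also passed only in cluster 6, and had adjusted p = 0.740, 0.783 and 0.783 with an estimated correlation. Naive and memory T genes lost their call there (adjusted p 0.534). Of the 226 lower genes, 190 were also lower in tumour-like cells, and 34 of these were higher-level there. Of the 143 higher genes, 93 were also higher in tumour-like cells, and 10 of these were higher-level there.

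Under anti-PD-1 the guide comparison asked whether Igfbp5 loss changes immune infiltration, and here 1 library stood in each group, so values carry no test. Tumour-like cells of the library labelled sgIgfbp5 had 159.9 CPM of Igfbp5 (156.8 to 163) against 318 (311 to 325) in sgScr, the opposite of the untreated libraries. T-like cells made up 1.24% (133 of 10729, 1.04 to 1.47) against 0.599% (40 of 6675, 0.428 to 0.815), a ratio of 2.07 (1.45 to 2.94). At a Leiden resolution of 2 the ratio was 4.51. Macrophage-like cells made up 2.45% against 0.974%, tumour-like cells 90.6% against 92.0%, and unnamed clusters 5.14% against 6.04%. Among named non-tumour cells, T-like cells made up 29.4% and 29.9%. Endothelial-like cells numbered 10 and 6, too few for gene values.

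In tumour-like cells under anti-PD-1, antigen-presentation, interferon and low-oxygen genes stood lower in the library labelled sgIgfbp5. MHC class I genes had a median log2 ratio of -0.24 (14 of 19 lower, below all 10000 random lists matched on expression), and H2-K1, a class I heavy chain gene, had 246 CPM (242 to 249.7) against 516 (507 to 525). Interferon genes had a median of -0.11 (20 of 28 lower, below all random lists), with Iigp1 at 19.2 CPM against 67.5. Hypoxia and glycolysis genes had a median of -0.42 (21 of 22 lower, below all random lists), with Vegfa, the main vessel growth factor gene, at 206 CPM (203 to 209.9) against 441 (433 to 449.7). In the untreated libraries this list stood higher with the sgIgfbp5 label. Mitochondrial genes took 1.28% of UMIs in these tumour-like cells with the sgIgfbp5 label and 2.12% in sgScr. Chemokine genes had a median of only 0.06 (6 of 7 higher), yet stood at percentile 99.95 of random lists. Neuroendocrine genes had 0.01, non-neuroendocrine genes 0.04 (percentile 96.7), IGF axis genes 0.01 and checkpoint ligands -0.02. Proliferation genes had 0.00 (14 of 27 higher), with Mki67 at 647 CPM against 1146. Clusters 0 and 4 held 27.4% and 15.2% of tumour-like cells with the sgIgfbp5 label and 3.81% and 3.23% in sgScr, and clusters 1, 3 and 5 held 24.4%, 19.9% and 17.4% in sgScr.

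T-like and macrophage-like cells under anti-PD-1 gave small counts. In T-like cells cytotoxicity genes had a median log2 ratio of 0.49 (8 of 12 higher, percentile 96.4 of random lists), exhaustion genes 0.33 (92.9), regulatory genes 0.40 (90.4), naive and memory genes -0.30 (9.93), interferon genes 0.17 (71.1) and proliferation genes 0.84 (6 of 6 higher, 97.4). Ccl4 had 189 CPM (142 to 246) with the sgIgfbp5 label and 17.8 (0.450 to 99.1) in sgScr, and Gzmb, the granzyme B gene, 105 against 53.4. Cd8a had 105 CPM against 160, and Foxp3, the regulatory T cell factor, 17.5 against 107. The sgScr T-like cells held 56228 UMIs in all, and LUCI2LTR, a feature of the reference that the labels do not describe, had 378 and 943 CPM in the T-like cells of the libraries labelled sgIgfbp5 and sgScr, and 1514 and 1796 in their tumour-like cells. In macrophage-like cells Arg1 had 58.5 CPM (44.5 to 75.4) against 540.3 (428 to 673) and Mmp12, a macrophage elastase gene, 461 (419.9 to 505) against 1826 (1614 to 2059). Immune-suppressive genes had a median of -0.18 (9 of 15 lower, percentile 5.79), immune-activating genes -0.10, MHC class I -0.20, MHC class II 0.07, interferon -0.06, TNF and NF-kB 0.18 and checkpoint ligands -0.17.

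Adding anti-PD-1 to OSI-906 asked how immune and tumour cell states move under combined treatment, again with 1 library per group and no test. T-like cells made up 19.95% (2488 of 12471, 19.3 to 20.7) with anti-PD-1 and 4.05% (468 of 11558, 3.70 to 4.42) without, a ratio of 4.93 (4.48 to 5.42). NK-like cells made up 7.22% against 1.93%, neutrophil-like cells 3.32% against 0.0346% (414 and 4 cells), macrophage-like cells 4.33% against 2.98% and dendritic-like cells 1.15% against 0.649%. Tumour-like cells made up 52.7% against 83.5%, and unnamed clusters 8.07% against 4.88%. Differences between these libraries may belong to the library and not to the treatment.

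In tumour-like cells with OSI-906 and anti-PD-1, interferon and antigen-presentation genes stood far higher than with OSI-906 alone. Interferon genes had a median log2 ratio of 0.97 (35 of 35 higher, above all random lists), with Iigp1 at 517 CPM (513 to 522) against 13.6 (13.03 to 14.1). MHC class I genes had a median of 1.53 (19 of 19 higher, above all random lists), with B2m, the light chain gene, at 1477 CPM against 505 and the immunoproteasome gene Psmb8 at 468 against 101. Genes of class II, Cd74 and H2-Aa, had 960.3 CPM against 34.6 and 501 against 19.6. Cd274, which encodes the PD-1 ligand PD-L1, had 47.1 CPM (45.8 to 48.4) against 9.90 (9.44 to 10.4), and Cxcl10, a T cell attractant, 129.6 against 7.46. Myc, a growth regulator gene, had 20.7 CPM against 146, and proliferation and hypoxia lists had medians of -0.28 and -0.23. Igfbp5 had 111 CPM (109 to 113) against 233 (230.5 to 235). Chemokines had 0.16 (also above all random lists), checkpoint ligands 0.06 (percentile 99.2), neuroendocrine genes -0.05, non-neuroendocrine genes -0.01 and the IGF axis -0.01. Of the T and NK cell genes, Cd8a had 1.72 CPM against 0.115 and Gzmb 10.3 against 0.349 in these tumour-like cells, where dendritic markers stood at 4.95% and 5.06% of their level in dendritic-like cells. Cluster 3 held 25.01% of tumour-like cells with anti-PD-1 and 0.943% without, and cluster 0 held 2.10% and 26.9%. Clusters 1 and 8, named tumour-like only in the second clustering, held 14.5% and 5.29% with anti-PD-1 and 0.891% and 0.249% without.

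**Figure D5:**
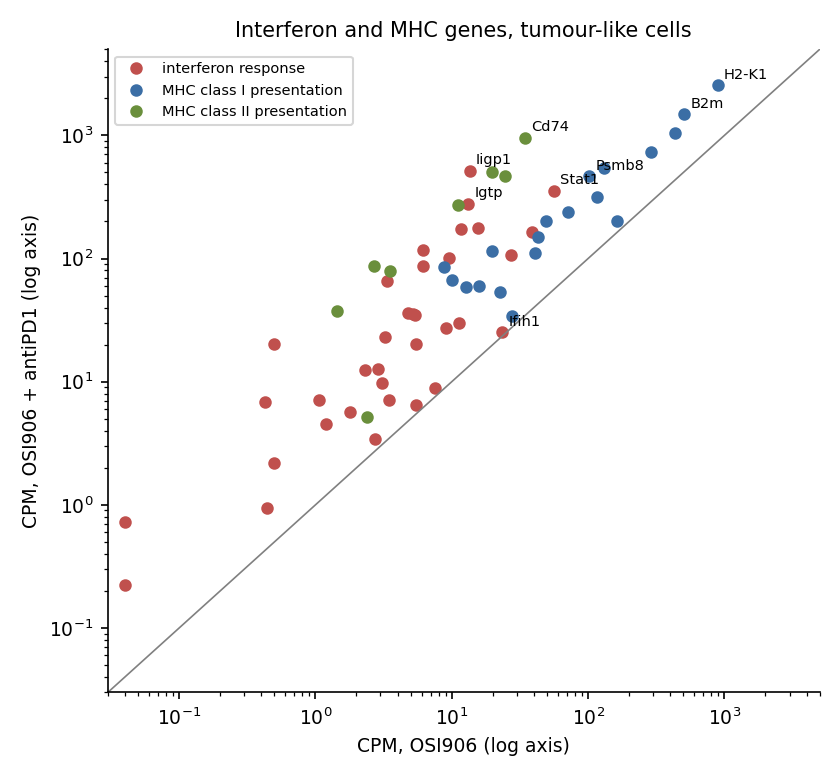
CPM in tumour-like cells of interferon and MHC genes with OSI-906 and anti-PD-1 (vertical log axis) against OSI-906 alone (horizontal log axis), one point per gene, with the line of equality. All 35 interferon and 19 MHC class I genes measured lie above the line.

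T-like cells with OSI-906 and anti-PD-1 carried more granzyme RNA. Gzmb had 2879 CPM (2849 to 2910) against 550.3 (521 to 581), Gzma 5082 against 1349 and Gzmk 386 against 123, each a gene of cytotoxic granules. Cytotoxicity genes had a median log2 ratio of 0.60 (17 of 23 higher, above all random lists), and naive and memory genes -0.41 (15 of 17 lower, percentile 0.420), with Tcf7, a factor of memory-like T cells, at 53.3 CPM against 133. Cd8a had 466 CPM against 245, Cd4 48.5 against 103, Pdcd1 414 against 184, Foxp3 25.7 against 37.4 and Ifng 108 against 154. Exhaustion genes had a median of -0.18, regulatory genes -0.19, interferon genes -0.19 and proliferation genes -0.13. Clusters 2 and 3 held 27.5% and 27.0% of T-like cells with anti-PD-1 and 11.1% and 10.7% without, where clusters 6 and 7 held 35.0% and 26.1%. In NK-like cells Gzmb had 792 CPM against 274, and cytotoxicity and interferon genes had medians of 0.12 and -0.02. LUCI2LTR had 44.9 CPM in T-like cells against 37.0, and 679 against 403 in tumour-like cells.

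Myeloid and stromal cells shifted in other ways. In macrophage-like cells immune-activating genes had a median of 0.42 (13 of 18 higher, percentile 99.99), with Nos2, the inducible nitric oxide synthase gene, at 179.7 CPM against 7.96 and Tnf at 491 against 150.1. Il12b had 0 CPM against 80.03. MHC class I genes had a median of 0.50 (15 of 19 higher), MHC class II 0.25, TNF and NF-kB 0.15, chemokines 0.14, interferon -0.03, checkpoint ligands -0.20 and immune-suppressive genes -0.27, with Folr2 at 5.90 CPM against 145, Retnla at 87.7 against 581 and Arg1 at 239 against 38.2. Cluster 16 held 29.4% of macrophage-like cells with anti-PD-1 and 4.36% without. In fibroblast-like cells interferon genes had a median of -0.67 (28 of 32 lower, below all random lists), matrix genes -0.50 (13 of 19 lower), chemokines 0.33 and the IGF axis 0.14. In dendritic-like cells MHC class I had 0.28, MHC class II 0.35, interferon 0.12 and chemokines 0.04. Hist1h1e, a linker histone gene, had log2 ratios of -3.43 in tumour-like, -2.92 in T-like, -2.79 in NK-like and -2.71 in fibroblast-like cells.

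The comparison of OSI-906 with anti-PD-1 against sgScr with anti-PD-1 cannot separate the drug from the preparation. Ribosomal protein genes took 17.1% and 14.2% of UMIs in the OSI-906 libraries and 1.39% and 1.46% in the guide libraries under anti-PD-1. T-like cells made up 19.95% against 0.599%, a ratio of 33.3 (24.4 to 45.4), or 156 at a Leiden resolution of 2. In tumour-like cells MHC class I genes had a median log2 ratio of 2.597 where matched random lists had -0.64, and interferon genes 1.39 where random lists had -0.13. H2-Q7, a class I gene, had 731 CPM against 0.557, and Igfbp5 111 against 318. Cytotoxicity and exhaustion genes of T-like cells had medians of 1.58 and 0.98 where random lists had -0.53 and -0.79.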

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

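The tests of one lower endothelial share, of a wrong guide label and of a shift of the whole library were chosen only after the result was seen, as were the counting intervals and the share of cells in the test of tumour clusters.

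Igfbp5 moved in opposite directions in the guide comparisons with and without anti-PD-1. In tumour-like cells its log2 ratio was 0.92 and 1.02 in the libraries labelled sgIgfbp5, each over sgScr, and -0.95 in the library labelled sgIgfbp5 with anti-PD-1 over sgScr with anti-PD-1. The difference was not tested, since 1 library stands in each group under anti-PD-1 and the kits differ. Clusters of tumour cells that differ between the libraries cannot be told apart from a change within clusters: Igfbp5 was higher in both libraries labelled sgIgfbp5 in 5 of the 5 tumour clusters that all 3 libraries share, but beyond the counting intervals in 2 of them, and the 5 hold 5.55% of the tumour-like cells of sgScr. A wrong guide label in the 5′ set cannot be told apart from a guide that leaves the transcript in place: the ratio of -0.95 would go with low transcript in edited tumours, but it rests on 1 library per group.

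Igf1r, the gene of the receptor that OSI-906 inhibits, also moved in opposite directions, in macrophage-like cells. Its log2 ratio was 0.41 and 0.64 in the libraries labelled sgIgfbp5 over sgScr, and -0.64 under anti-PD-1. The difference was not tested. With edgeR the change without anti-PD-1 was 0.57 (SE 0.38, adjusted p 0.751).

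Features of the reference that the labels do not describe carried signal that no comparison uses, given here as ranges over libraries of both kits, with no test between them. In tumour-like cells LUCI2LTR ranged from 362 CPM in sgScr to 1796 in sgScr with anti-PD-1 across the 7 libraries. CAS9 ranged from 16.1 CPM in sgIgfbp5 replicate 2 to 42.3 in sgScr with anti-PD-1. V2TC ranged from 38.0 CPM in sgIgfbp5 replicate 1 to 132 in OSI-906 with anti-PD-1. All lay above the level that a count of 0 allows, at most 0.119 CPM for LUCI2LTR in sgScr with anti-PD-1.

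Some epithelial and lung genes were higher in SCLC endothelium, and alveolar markers in replicate 1 only (type 2 at 51.9 and 0.617 times the NSCLC mean in replicates 1 and 2). Of the 1310 higher and 370 lower genes at an unadjusted p under 0.05, 1081 and 280 were found with 10 CPM or more in a class of the 5′ libraries. Only these were counted. The higher ones were mostly genes of other cells: 78.4% of 1081 had an endothelial-like level under 25% of that in another class. This held for 21.8% of the 280 lower genes (Fisher's exact test, 2-sided p 4.11e-69, genes not being independent) and 28.0% of all 12239. These classes came from SCLC tumours only, so RNA of NSCLC tumour cells in the NSCLC preparations could not be counted. The 21.8% may therefore be too low, and the Fisher p overstates the contrast in that case. Against all genes, the 78.4% among higher genes still stood above the 28.0%. RNA from other cell types in the SCLC preparations is therefore a candidate explanation, and no class accounts for most of these genes: the class with the highest level was mesothelial-like for 141 of the 1081, club- or ciliated-like for 119, tumour-like for 114, alveolar type 2-like for 113, alveolar type 1-like for 104 and fibroblast-like for 60, beside alveolar type 2 markers at 10694 CPM in SCLC replicate 1 and fibroblast markers at 13872 in replicate 2, in cells whose isolation the labels do not describe. One lower endothelial share in both SCLC libraries as the whole cause was not settled by the marker lists. Of 21 lists of other cell types, 5 lay below every NSCLC library in an SCLC library. Spread between libraries alone can give such a count. The values were 1925 against at least 2120 CPM for fibroblast, 232 against 264 for dendritic and 1.58 against 1.91 for NK. Alveolar type 1 had 104 against 138, and mast or basophil 52.0 against 120. Endothelial sums overlapped between the groups, at 14208 and 8954 CPM in SCLC and 7068 to 14326 in NSCLC. A difference between the vessels of the tumour types, which the design names, stays open and was not tested apart from this.

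Interferon and MHC class I genes were higher in tumour-like cells with OSI-906 and anti-PD-1. RNA from immune cells in tumour droplets was argued against: for 49 of 54 members that rose, the level predicted from immune markers was under 20% of the rise (median 3.49%, highest 65.6% for Gbp5). For the interferon list, a shift of the whole library was argued against as well. The highest interferon median among 5 other classes was 0.12, in dendritic-like cells, against 0.97 in tumour-like cells. MHC class I genes were not part of that test. Their medians were 0.50 in macrophage-like and 0.28 in dendritic-like cells against 1.53 in tumour-like cells, so part of their rise may be shared. Hist1h1e fell in tumour-like, T-like, NK-like and fibroblast-like cells alike, so some genes did differ across classes. For MHC class II genes the predicted level was under 20% of the rise for 5 of 8 members (median 16.1%, highest 549%). Here the estimate is not reliable, since 549% is more than the whole rise. Its dendritic part rests on markers at 4.95% and 5.06% of their dendritic-like level in tumour-like cells, with and without anti-PD-1. The other immune classes had at most 0.424%. Whether tumour-like cells express some of these dendritic markers was not tested. RNA from immune cells in tumour droplets therefore cannot be told apart from expression in tumour-like cells for these genes. A response of the tumour cells to the added anti-PD-1 is a hypothesis that 1 library per group cannot separate from a difference between tumours.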

How the results depend on the processing

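Restricting the bulk test to genes with an endothelial-like level and restricting macrophage-like cells to their shared cluster were chosen after seeing the data.

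With edgeR, 0 bulk genes passed under each scaling, the filter of 10 counts in 2 libraries, the non-robust fit and the replicate block (1311 at an unadjusted p under 0.05), and 4 of 18765 passed with no filter (Cgn, Tnxb, Krt7 and Ptprf). DESeq2 called 825, and the cause was not tested. In simulated data many of its calls fell on unchanged genes (91 of 14494). Leaving out 1 library gave 0 to 98 genes, with 60 without SCLC replicate 1 and 98 without SCLC replicate 2, fits in which the spread comes from NSCLC alone. Among genes with an endothelial-like level 0 of 8817 passed with edgeR (452 at an unadjusted p under 0.05, 233 higher and 219 lower, against 1310 and 370 of all genes) and 92 with DESeq2 (64 higher, 28 lower). The labels give both groups the same replicate numbers but do not say that a number marks a shared animal or batch, so the unpaired fit was planned. Deviations from the group mean correlated across genes at -0.117 and 0.0897 in the 2 pairs (genes are not independent replicates). This check cannot settle the pairing, since the deviations of the 2 SCLC libraries mirror each other.

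Of the 27 bulk lists, 6 passed, 8 did with the replicate block, 5 to 10 did when 1 library was left out, and 0 did with an estimated correlation, which allows for members that move together. For T cell cytotoxicity the adjusted p ranged from 5.59e-05 to 0.631 when 1 library was left out, and for proliferation from 4.03e-16 to 0.350. For both the highest value, with the direction turned, came without SCLC replicate 1, and the cause was not tested.

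In tumour-like cells, where edgeR called 0 genes (2322 at an unadjusted p under 0.05), DESeq2 called 586 and edgeR with no filter called 1256 of 23832. In T-like cells (32 genes) DESeq2 called 0 (43 at an unadjusted p under 0.05), no filter gave 21 and no doublet removal 74. In macrophage-like cells (369 genes) DESeq2 called 43, the looser cell filter gave 185, a Leiden resolution of 2 gave 214, and the shared cluster gave 214, in which Arg1 turned to 0.22 (adjusted p 0.971). With an estimated correlation 0 lists passed in tumour-like, 0 in T-like and 0 in macrophage-like cells. With 1 residual degree of freedom this could hardly turn out otherwise, so no conclusion is drawn from it. The cause was not tested for these counts. Leaving out a library labelled sgIgfbp5 leaves 1 against 1 and gives values with no test.

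The T-like share ratio under anti-PD-1, 2.07 for the guide libraries, was 4.51 at a Leiden resolution of 2 and 1.92 to 2.13 under the other alternatives. For OSI-906 with anti-PD-1 over sgScr with anti-PD-1, 33.3 became 155.8 at a Leiden resolution of 2 and lay between 24.5 and 32.8 otherwise. The cause was not tested. Against OSI-906 alone it lay between 4.89 and 4.97. The T-like share difference in the 5′ set, -1.46 percentage points, ranged from -3.06 to 0.145 when 1 library labelled sgIgfbp5 was left out, beside a spread between them of 2.26.

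Of 1020 values for 85 named bulk genes under the alternatives, 926 kept direction and side of the threshold, 65 newly passed and 29 changed sign without a call in either fit. Of 216 values for lists, 154 kept both, 12 lost and 12 gained a call, 36 changed sign from a result with no call and 2 turned a call. For 128 named single-cell results, 794 of 978 values kept both, 102 lost and 48 gained a call, 33 changed sign from a result with no call or moved by over 1 SE in a single pair of libraries, and 1 turned a call. For single-cell lists 57 of 70 kept both and 13 lost the call. For genes and lists compared 1 against 1, 966 of 1157 values kept sign and stayed within 0.25 on the log2 scale and 191 did not.

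Depth and spread both differ between the cell classes, and the simulations did not vary depth alone. In simulated data edgeR called 4.92% of 61 genes changed 2-fold and 44.3% of 61 changed 4-fold in T-like cells, and 3.23% of 62 and 58.7% of 63 in macrophage-like cells, against 55.2% of 67 and 92.5% of 67 in tumour-like cells. In bulk edgeR called 8 of 14246 unchanged genes, beside 1, 21 and 49 genes changed 2-fold, 4-fold and 8-fold. DESeq2 called 91 of 14494 unchanged genes, beside 10, 50 and 63 changed ones, so many of its calls were false. Among unchanged genes edgeR also called 62 of 17490 in tumour-like, 1 of 7864 in T-like and 2 of 9803 in macrophage-like cells.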

Other observations

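Igf1, the ligand gene, had higher levels in macrophage-like than in tumour-like cells, while the receptor genes had levels in both. On unscaled totals of the 5′ libraries Igf1 had 402 and 373 CPM in macrophage-like cells of sgIgfbp5 replicates 1 and 2 and 211 in sgScr, and 2.74, 1.35 and 4.13 in tumour-like cells. In the OSI-906 libraries Igf1 was highest in fibroblast-like cells, at 322 CPM with anti-PD-1 and 221 without, beside 24.8 and 66.5 in macrophage-like and 0.332 and 0.412 in tumour-like cells. Igf1r had 609 CPM in fibroblast-like and 376 in tumour-like cells of sgIgfbp5 replicate 2, and 155, 183 and 114 in macrophage-like cells of sgIgfbp5 replicates 1 and 2 and sgScr. Insr had 218, 194 and 257 CPM in their tumour-like cells and 272.5, 204 and 217 in their macrophage-like cells.

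Endothelial-like cells could be compared only between sgIgfbp5 replicate 2 (287 cells) and sgScr (42 cells), as values. The tissue sampled differed as well. Replicate 2 held 419 alveolar type 1-like, 301 alveolar type 2-like and 356 mural-like cells, against 0, 0 and 47 in sgScr. The values below cannot separate the guide label from that difference. Igf1r had 792 CPM (95% interval 722 to 868) against 331 (261 to 413), and Insr 533 (476 to 596) against 1153 (1020.1 to 1299). Igfbp5 had 86.9 CPM (64.7 to 114) against 17.0 (4.62 to 43.4), Cldn5 104 (79.5 to 134) against 50.9 (26.3 to 88.9) and Icam1 66.5 (47.3 to 90.9) against 25.4 (9.33 to 55.4). The intervals of Cldn5 and of Icam1 overlapped between the libraries. Plvap had 133 against 144, Abcb1a 97.1 against 84.8 and Vcam1 17.0 against 33.9 CPM, also with overlapping intervals. Lymphatic endothelial-like cells had 251 CPM of Igfbp5 (151 to 391, 33 cells) against 2112 (1704 to 2587, 20 cells), and mesothelial-like cells of sgScr had 313 (276 to 354).

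LUCI2LTR was not limited to tumour-like cells. In sgIgfbp5 replicate 2 it had 752 CPM (683 to 825) in endothelial-like cells, 567 (559 to 575) in tumour-like, 331 in mural-like, 308 in fibroblast-like and 128 in macrophage-like cells. V2TC had 25.6 CPM in endothelial-like cells of that library against 62.7 in tumour-like cells. In sgScr LUCI2LTR had 174 CPM (125 to 236) in endothelial-like cells against 362 in tumour-like cells.

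Some clusters fit no marker list. In the 5′ set, a cluster of 42 and 698 cells in sgIgfbp5 replicates 1 and 2 carried LUCI2LTR at 504.04 and 483 CPM and Smoc2 at 46.1 and 134. In the guide libraries under anti-PD-1, a cluster of 119 and 112 cells in those labelled sgIgfbp5 and sgScr carried LUCI2LTR at 1478 and 1801 CPM, Smoc2 at 213 and 211, and Wfdc2 at 88.6 and 101. In the OSI-906 libraries a cluster led by Cd163l1 and Il17a held 124 cells with anti-PD-1 and 10 without, and a cluster with Xcl1 and Ncr1 among its leading genes held 86 and 15.

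Ribosomal protein genes took 1.52%, 1.54% and 1.05% of UMIs in sgIgfbp5 replicates 1 and 2 and sgScr. Mitochondrial genes took 0.475%, 0.390% and 0.422% there, 1.32% and 2.14% in the libraries labelled sgIgfbp5 and sgScr with anti-PD-1, and 1.97% and 2.68% in OSI-906 with and without anti-PD-1.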
